A study of Mus musculus with 6 samples.

How the data were processed

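Adrenal gland total RNA of wild-type mice (PACAP +/+) and of mice lacking PACAP (PACAP -/-), both on the mixed 129XC57BL6 F2 background, was hybridised to 6 spotted cDNA arrays. PACAP, pituitary adenylate cyclase-activating polypeptide, is the neuropeptide encoded by Adcyap1. Each array held 1 wild-type RNA labelled with Cy5 (red) and 1 knockout RNA labelled with Cy3 (green), per the labels. No array had the dyes exchanged, so that a dye effect specific to a clone has the same sign on every array as a genotype effect. The labels number the arrays as repeats and do not say whether each held RNA of separate animals. P-values therefore measure the spread between these 6 arrays, which may be technical in part.

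Per the series design text, slides were scanned with a GenePix 4000A scanner, images were analysed with IPLab and a FileMaker Pro database, background was subtracted, ratios were normalized, and ratios were used only where their combined quality score exceeded 0.3. Software versions were not given in the sources used here. Each scanner file has 37632 spots in 48 print blocks, the areas each printed by 1 pin. The deposited red and green intensity columns already had the local background subtracted: the 768 empty positions had a median of 1.0 in both channels, and up to 45.0% of the red values of an array lay below that array's own background column. The deposited calibrated ratio was red over green divided by 1 constant per array, which lay between 0.220 and 0.783. The deposited quality score of each ratio lay between 0 and 1. The series value table holds the authors' log2 ratios of red over green. In 100% of the 2245 rows that share a clone accession with 1 spot, and on each of the 6 arrays, its values equalled (within 0.01) the log2 ratio after the background had been subtracted a second time from the deposited intensity, values below 1.0 had been raised to 1.0, and the ratio had been divided by the array's constant. Its scale and direction are thereby known. Its columns are not centred, with medians of -0.10, -1.65, -0.84, -2.59, -0.67 and -1.11 on arrays 1 to 6.

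Log2 ratios of knockout over wild type (green over red) were computed from the deposited intensities. No further background correction was made, because the columns were already corrected, as the plan fixed before the data were examined had allowed for. Spots with a quality score of 0.3 or less and 1048 control or empty spots were left out. Ratios were normalized within each array by global loess. Spots of the same clone were averaged, and clones with values on at least 4 of the 6 arrays were tested against 0 with lmFit and eBayes of limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment over 28708 clones and a threshold of 0.05. Print-tip loess, which fits each print block separately, was among the alternatives fixed beforehand. Its result is given beside the counts and list means and beside most named genes, since it moved the count of clones by more than 1.5 times. Python 3.11.15 with scipy 1.17.1 served for the exact permutation tests.

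Genes were named through the annotation table of the value table's probes, whose rows were linked to spots by their values on all 6 arrays (within 0.002). Of 35873 rows, 35793 (99.8%) matched 1 spot, and the 2235 linked rows with a shared accession all met the spot of that accession. Of 36013 clones, 22364 had 1 gene, 1105 had several and 12544 had no listed gene. Several-gene clones were not named. Symbols were updated by gene ID through the RefSeq table of the assembly GRCm38.p6, which held 11616 of the 11837 named genes. Annotation of this kind can be old: among 3903 named clones in UniGene clusters with at least 3 named clones, 422 (10.8%) had another gene than most clones of the cluster given in the scanner files. Gene positions, used only to find genes near Adcyap1, came from the same RefSeq table, and no coordinates are printed.

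The text names Adcyap1, the 10 genes with the largest higher and the 10 with the largest lower log2 ratio among clones past the threshold with 1 sign on every array measured, and from each gene list the 2 members with the largest ratio past the threshold or, if none passed, the member with the smallest p. Other genes were named after their values were seen, where a count of 5 or fewer is spelled out or an example is given. Before the data were examined, 24 gene lists were fixed. They covered PACAP and VIP ligands and receptors, catecholamine synthesis, chromaffin lineage transcription factors, secretory granule proteins, exocytosis and neuronal proteins, steroid hormone synthesis, cholesterol synthesis, immediate early and cAMP-responsive genes, stress response, oxidative phosphorylation, cytosolic ribosomal proteins, cell cycle and interferon-stimulated genes. The remaining lists held markers of the X-zone, endothelium, macrophages, lymphocytes, erythroid cells, adipocytes, fibroblasts and capsule, Schwann and sustentacular cells, skeletal muscle, kidney and sex-linked genes. Each list with at least 3 measured genes was tested with limma's camera in its preranked form, on the moderated statistics of 1 clone per gene (that of highest mean signal), with a preset correlation of 0.01 and adjustment over 22 lists. Camera with an estimated correlation and fry used the genes measured on all 6 arrays. A call lost with an estimated correlation therefore cannot be credited to the correlation alone. For the interferon list after print-tip loess the estimate equalled the preset 0.01, yet camera's unadjusted p was 0.121 against 0.048 with the preset. Genes within 10 Mb of Adcyap1 were compared with all other genes by a two-sided Fisher's exact test.

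Alternatives fixed beforehand changed the background correction, the loess, the scaling between arrays, the quality filter, the number of arrays required, the clones tested by signal, the source of the values, the variance model, array weights, the pairing of the channels and the threshold, and left out each array in turn. Normexp with an offset of 50, the omission of arrays 2 and 4, print-tip loess with arrays left out or weighted, and the unfiltered ratio of Adcyap1 were added after seeing the data.

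The clone test was tested on simulated data at the signals of the real spots, with 200 changed spots drawn only from those above a minimum mean signal. With 28708 clones tested, it recovered 99 of 99 clones changed by 1 on the log2 scale. It recovered 98 of 98 changed by 0.5, and 5.3% of its calls were false. With a gradient over the print blocks added, the same on every array, global loess made 17622 false calls and print-tip loess 10. The simulated noise was independent between spots, equal on all arrays and without dye effects. Recovery among the weakest spots was not examined, since none of them was drawn for a change. On the real arrays the SD of the log2 ratios ran from 0.342 to 0.691, so these rates cannot be carried over to the real data. The list test, run on 10400 simulated genes, called the 1 list of 20 genes shifted by 0.3 and 0 of 20 random lists. The shift was added to the test statistics of genes simulated without correlation. In the real lists the estimated correlation reached 0.211 with global loess and 0.319 after print-tip loess, both for stress response. The simulation therefore does not show how the test behaves on such lists.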

Results

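Gene expression in the adrenal gland was compared between wild-type mice and mice without PACAP, a neuropeptide that acts as a transmitter from the splanchnic nerve onto the catecholamine-secreting chromaffin cells of the adrenal medulla. The series asks which adrenal genes depend on PACAP. Each of 6 arrays compared 1 wild-type with 1 knockout RNA, and the precision is limited by that number. The quality filter kept 30214, 26027, 29798, 28230, 28270 and 31960 of the 37632 spots on arrays 1 to 6. The median background-subtracted red (wild-type) signal, as a multiple of its local background, was 4.74, 1.36, 2.05, 1.13, 2.08 and 1.63 on these arrays, while that of the green (knockout) signal lay between 5.33 and 6.99. All ratios are knockout over wild type on the log2 scale, and each could hold a clone's dye effect, because knockout RNA carried Cy3 on every array.

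Adcyap1, the targeted gene, gave no check of the labels. Its 1 clone passed the quality filter on 2 of the 6 arrays, with a mean log2 ratio of -0.08 and no test. Without the filter its ratio ranged from -1.27 to 0.93 between arrays, with a mean of -0.18 ± 0.24 (SE, n = 6; adjusted p = 0.603). The background-subtracted red signal of this clone was smaller than the local background on 4 of the 6 arrays. Where the clone lies relative to the deleted part of the gene is not given in the sources used here.

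Across the array, 8732 of 28708 clones (30.4%) passed the threshold, 4646 of them higher and 4086 lower in the knockout. The count depended on where clones were printed. The mean log2 ratio of a print block, over 222 to 602 of its spots, ranged from -0.55 to 0.70. Differences between the 48 blocks made up 48.7% of the variance of the mean log2 ratio. After print-tip loess, 3259 clones (11.4%) passed, 1934 higher and 1325 lower, and 2017 of the 8732 remained past the threshold in the same direction. The deposited value table gave 90 clones, all 90 higher, against 53.2% higher with the scanner values. Without array 4 the count with global loess was 4478, and without arrays 2 and 4, the arrays with the weakest red signal, it was 2234. After print-tip loess it was 1 without array 2, 1 without array 3, 19 without array 4 and 1 without array 6. Armt1 was past the threshold in all 4 of these fits, and it was the only clone to pass without array 2, 3 or 6. Every other call of a single clone after print-tip loess given below therefore ended, or could no longer be tested, when array 2, 3 or 6 was left out.

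**Figure D1:**
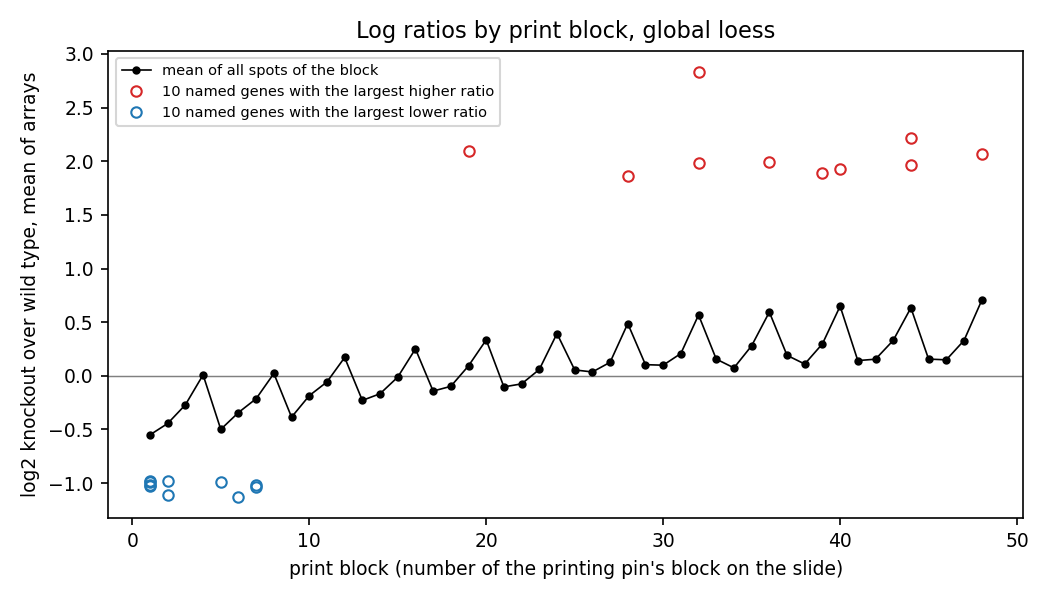
Mean log2 ratio of knockout over wild type (vertical axis) of each of the 48 print blocks (black points, horizontal axis), over 222 to 602 spots per block. Red circles are the 10 named genes of largest higher ratio and blue circles the 10 of largest lower ratio. All values are means over the arrays after global loess. Block means run from -0.55 to 0.70, the 10 lower genes lie in blocks 1 to 7 and the 10 higher genes in blocks 19 to 48.

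The largest higher ratio among named genes belonged to Armt1, an acidic residue methyltransferase, at 2.83 ± 0.13 (SE, n = 6; 7.12-fold, adjusted p = 1.03e-07), higher on 6 of 6 arrays. It was followed by Ctnnd1, which encodes the cadherin-binding p120 catenin (2.21 ± 0.26), Fnip1, a partner of folliculin (2.09 ± 0.16, n = 4), Tspyl2 (2.07 ± 0.20) and the small GTPase gene Rab23 (2.00 ± 0.25). The Wnt signalling gene Dvl1 (1.98 ± 0.27), the translation elongation factor gene Eef1a1 (1.97 ± 0.21), Aifm1, which encodes a mitochondrial flavoprotein (1.92 ± 0.23), the kinesin light chain gene Klc1 (1.89 ± 0.23) and Rtl8b (1.86 ± 0.25) completed the 10, each higher on every array measured. All 10 also passed after print-tip loess, at 1.06 to 2.32, with Armt1 at 2.32 ± 0.17 (adjusted p = 0.00278). The 9 other than Armt1 had adjusted p between 0.0196 and 0.0443 there. For Ctnnd1, another clone of the same gene passed in the opposite direction with global loess, whereas 11 of the 12 Eef1a1 clones passed in the same one. Of the 10 genes 9 had other clones, but only 4 had at least 2 clones that passed the same way.

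The 10 named genes with the largest lower ratio fell by less, to between -1.13 and -0.98. They were Fbxo15 (-1.13 ± 0.23, SE, n = 5, adjusted p = 0.0041; the scanner files title this clone sarcoglycan alpha), Natd1, F8a, Suco, E330016L19Rik, the translation initiation factor gene Eif2b5, the homeobox gene Nkx6-1 (-0.99 ± 0.15, n = 6, adjusted p = 0.00116), AU015228, Cnot6l, a subunit of the deadenylase complex, and Taf1, a subunit of the general transcription factor TFIID. Each was lower on every array measured. Their spots all lay in print blocks 1 to 7, the end of the slide with the lowest block means. After print-tip loess 5 of the 10 passed (F8a, E330016L19Rik, Eif2b5, Nkx6-1 and AU015228), and the 10 ratios lay between -0.59 and -0.20. Of the 10 genes 7 had other clones, but only 2 (Fbxo15 and Eif2b5) had at least 2 clones that passed as lower with global loess.

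Most genes of the chromaffin cell's secretory apparatus did not pass, and more of those that did were higher than lower. Of all clones, 30.4% passed with global loess, 53.2% of them higher. After print-tip loess 11.4% passed, 59.3% of them higher. Counts of passing members, here and in the lists below, are to be read beside these shares and do not by themselves set a list apart. Of 19 measured members of the list of secretory granule proteins and neuropeptides, 6 were higher, 1 was lower and 12 did not pass (7 passed when adjusted over the list alone). The 6 were Scg3, which encodes secretogranin III (1.36 ± 0.21, SE, n = 6; 2.56-fold, adjusted p = 0.00118), Chga, which encodes chromogranin A (1.26 ± 0.20, n = 6, adjusted p = 0.00135), Chgb, Scg2, the amidating enzyme gene Pam and Ptprn2. Somatostatin (Sst) was lower, at -0.80 on the 4 arrays that measured it, and at -0.05 after print-tip loess. After print-tip loess Scg3 (1.22 ± 0.20, adjusted p = 0.0242), Chgb (0.70), Scg2 (0.89), Pam (0.42) and Ptprn (1.11) passed as higher and no member as lower, again with 7 adjusted over the list alone. The scanner files title the Scg2 clone as a patched homolog and the Ptprn clone as a DnaJ homolog. The clone used for Chga was at 0.39 ± 0.13 there and did not pass (adjusted p = 0.0769), while 2 of the 3 Chga clones did, of which the scanner files title 1 as another gene, Nedd4a. The list as a whole did not pass, at a mean of 0.26 (adjusted p = 0.295 in camera; 0.924 with an estimated correlation) or of 0.27 after print-tip loess (adjusted p = 0.0591; 0.746 with an estimated correlation). After print-tip loess it passed in 2 of the 6 fits that left out 1 array (lowest adjusted p = 0.0152). Without arrays 2 and 4 its mean was 0.21, or 0.16 after print-tip loess (adjusted p = 0.445 and 0.0961 in camera).

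Catecholamine synthesis, storage and uptake had 6 measured members, of which 1 was higher, 2 were lower and 3 did not pass, and 3 passed when adjusted over the list alone. Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, was at 1.10 ± 0.24 (SE, n = 6; 2.14-fold, adjusted p = 0.00518) and higher on 5 of 6 arrays. After print-tip loess it was at 0.65 ± 0.21 and no longer passed (adjusted p = 0.072), and without arrays 2 and 4 it was at 0.71 (adjusted p = 0.0665). The clones of the pteridine reductase gene Qdpr disagreed: that of highest signal was lower at -0.52 ± 0.16 (n = 5), but at 0.17 ± 0.18 after print-tip loess, and its other clone passed as higher at 0.56 with global loess. The lower call also ended without array 3, 4 or 5 (-0.56 to -0.40, adjusted p 0.0533 to 0.11). The print-tip ratio of the same clone ran from -0.01 to 0.32 with 1 array left out. The vesicular monoamine transporter gene Slc18a1 was lower in both, at -0.41 and -0.46 (n = 5), and 3 members passed when adjusted over the list alone after print-tip loess. The list's mean was 0.11 (adjusted p = 0.938), or 0.16 after print-tip loess (adjusted p = 0.723), and with global loess it was 0.33 without array 5, 0.06 without array 2 and 0.05 without array 4. None of the 5 measured chromaffin lineage transcription factors passed in either normalization, the smallest p belonging to Gata3 at -0.23 ± 0.12 (n = 6, adjusted p = 0.147; -0.11 after print-tip loess), and none of the 3 measured PACAP and VIP receptors and ligands passed. Vipr2 was at -0.19 ± 0.12 (n = 6, adjusted p = 0.254) and at 0.15 after print-tip loess. The transcription factor list had a mean of -0.05 (adjusted p = 0.823), or -0.04 after print-tip loess (adjusted p = 0.723), and ran from -0.10 without array 4 to -0.02 without array 1. The PACAP and VIP list had a mean of -0.01 (adjusted p = 0.921) and, with the other sign, of 0.05 after print-tip loess (adjusted p = 0.843). With global loess the mean was -0.32 without array 5 and -0.28 with no background correction, and after print-tip loess it ran from -0.07 to 0.07 with 1 array left out. For the PACAP receptor gene Adcyap1r1, the clone of highest signal was at 0.23 and did not pass, and another of its 3 clones passed at -0.50 with global loess but not after print-tip loess (-0.16).

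Of 29 measured exocytosis and neuronal genes, 7 were higher, 4 were lower and 18 did not pass (13 passed when adjusted over the list alone). The neurofilament gene Nefl was at 1.43 ± 0.25 (SE, n = 6, adjusted p = 0.00183) and the cell cycle inhibitor gene Cdkn1c at 1.19 ± 0.17 (n = 6, adjusted p = 0.000806), both higher on 6 of 6 arrays. The 4 lower members were Stmn3, Nefh, Chrna3 and Cacna1b, at -0.78 to -0.36, although another of the 3 Nefh clones passed as higher. After print-tip loess 6 were higher, Nefl (1.08), Cdkn1c (0.98), Map1b (0.56), Uchl1 (0.44), Syn2 (0.43) and Eno2 (0.36), none was lower, and 7 passed when adjusted over the list alone. The other Eno2 clone had passed as lower with global loess. The list's mean was 0.09 (adjusted p = 0.821; 0.15 without array 6), or 0.19 after print-tip loess (adjusted p = 0.0591), where it passed in 4 of the 6 fits that left out 1 array. With an estimated correlation it did not pass, at adjusted p = 0.924, or 0.687 after print-tip loess.

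**Figure D2:**
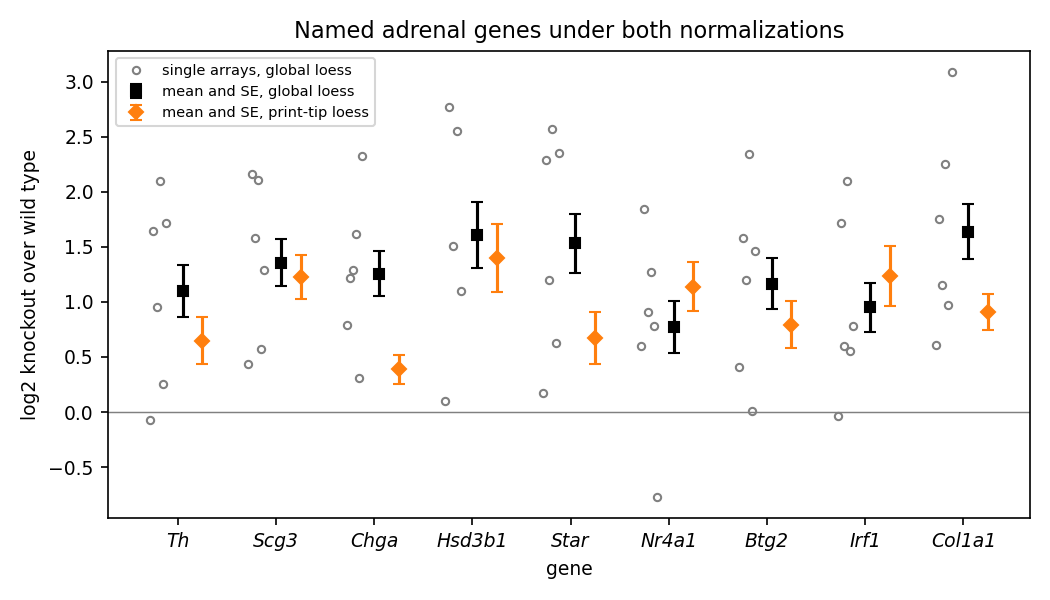
Log2 ratio of knockout over wild type (vertical axis) of 9 named genes (horizontal axis): single arrays after global loess (grey circles), and mean with SE after global loess (black squares) and after print-tip loess (orange diamonds). Th, Chga and Star moved from 1.10, 1.26 and 1.53 to 0.65, 0.39 and 0.67 with print-tip loess, while Scg3, Hsd3b1 and Nr4a1 were at 1.22, 1.40 and 1.14.

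Of 15 measured genes of steroid hormone synthesis, a function of the adrenal cortex, which the whole-gland RNA does not separate from the medulla, 4 were higher, 1 was lower and 10 did not pass (7 passed when adjusted over the list alone). Hsd3b1, which encodes 3-beta-hydroxysteroid dehydrogenase, was at 1.60 ± 0.30 (SE, n = 5; 3.04-fold, adjusted p = 0.00288) and higher on 5 of 5 arrays. Star, which encodes the protein that carries cholesterol into mitochondria, was at 1.53 ± 0.27 (n = 6, adjusted p = 0.00199), the side-chain cleavage enzyme gene Cyp11a1 at 1.16 (adjusted p = 0.00595) and the transcription factor gene Nr5a1 at 0.64 (adjusted p = 0.00942). Cyp17a1 was the lower member, at -0.74 on 4 arrays. After print-tip loess Hsd3b1 (1.40 ± 0.31, adjusted p = 0.0321) and Nr5a1 (0.62) kept their calls, the cholesterol uptake genes Scarb1 (0.85) and Npc1 (0.63) passed, and Star (0.67 ± 0.24, adjusted p = 0.0841), Cyp11a1 (0.72, adjusted p = 0.0712) and Cyp17a1 (-0.18) did not. After print-tip loess 7 passed when adjusted over the list alone. The list's mean was 0.25 (adjusted p = 0.657; 0.39 without array 1), or 0.33 after print-tip loess (adjusted p = 0.081), where it passed in 2 of the 6 fits that left out 1 array (lowest adjusted p = 0.0407). With an estimated correlation the adjusted p was 0.924, or 0.687 after print-tip loess. Without arrays 2 and 4 the mean was 0.24, or 0.17 after print-tip loess (adjusted p = 0.634 and 0.0961 in camera).

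Of 21 measured genes of cholesterol synthesis and uptake, 2 were higher (Fdps and Ggps1), 3 were lower (Hmgcs1, Msmo1 and Mvd) and 16 did not pass, with 4 passing when adjusted over the list alone. These calls rest on the clone of highest signal: the 2 other Hmgcs1 clones passed as higher (0.72 and 0.66), and another of the 3 Ggps1 clones passed as lower (-0.53). Mvd at -0.68 ± 0.24 lost its call without array 2, 3, 4 or 6 (-0.70 to -0.34, adjusted p 0.0861 to 0.149), the value nearest 0 being that without array 3, and Msmo1 moved from -0.61 ± 0.15 to 0.00 ± 0.08 with print-tip loess. Fdps alone passed after print-tip loess, at 0.68, also when adjusted over the list alone. The sign of the list's mean differed between the normalizations. It was -0.05 (adjusted p = 0.823; -0.02 without array 3, -0.03 without array 4 or 6), or 0.04 after print-tip loess (adjusted p = 0.65).

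Among 28 measured immediate early and cAMP-responsive genes, 8 were higher, 3 were lower and 17 did not pass (12 passed when adjusted over the list alone). The antiproliferative gene Btg2 was at 1.17 ± 0.23 (SE, n = 6, adjusted p = 0.00357) and the nuclear receptor gene Nr4a1 at 0.77 ± 0.24 (n = 6, adjusted p = 0.0267, higher on 5 of 6 arrays). The call of Nr4a1 ended without array 2, 3, 4 or 5 (0.56 to 0.77, adjusted p 0.0528 to 0.0934). Fosl2, Atf3 and Pde4b were the lower members, at -0.63 to -0.52, although 2 of the 4 Fosl2 clones passed as higher. After print-tip loess 7 were higher, namely Nr4a1 (1.14 ± 0.22, adjusted p = 0.0261), Btg2 (0.79), Bdnf (0.77), Jun (0.70), Crem (0.60), Klf6 (0.45) and Klf2 (0.42), and 2 were lower, Arc (-0.47) and Pde4b (-0.38), with 10 passing when adjusted over the list alone. The mean was 0.14 (adjusted p = 0.657), or 0.16 after print-tip loess (adjusted p = 0.355). Of 24 stress response genes, 6 were higher, 2 were lower (Fkbp5 and Mt2) and 16 did not pass, with 10 passing when adjusted over the list alone. The chaperone gene Hsp90aa1 was at 0.84 ± 0.13 (n = 6, adjusted p = 0.00111), but at 0.07 ± 0.09 after print-tip loess. The glucocorticoid-induced Fkbp5 was at -0.72 ± 0.20 (n = 5), at -0.44 without array 6 and at -0.10 after print-tip loess. The metallothionein gene Mt2 was lower in both (-0.58 and -0.57). After print-tip loess Hsp90b1 (0.60) and Calr (0.45) passed as higher and Mt2 and Dnajb1 (-0.29) as lower, with 7 passing when adjusted over the list alone. Dnajb1 passed in opposite directions in the 2 normalizations, being at 0.52 with global loess (adjusted p = 0.0161). The list's mean was 0.14 in both (adjusted p = 0.657 and 0.279). After print-tip loess it was 0.09 without array 2 or 4, without both arrays it was 0.06, or 0.02 after print-tip loess, and with median centring it was -0.01.

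Most genes of the translation and respiratory machinery did not pass, and more of those that did were higher than lower. Among all clones 30.4% passed with global loess, so these counts alone do not set the 2 lists apart. Of 62 cytosolic ribosomal protein genes, 18 were higher, 3 were lower (Rpl31, Rpsa and Rpl30) and 41 did not pass (21 passed when adjusted over the list alone). Another of the 5 Rpsa clones passed as higher. Rpl5 was at 1.08 ± 0.24 (SE, n = 6, adjusted p = 0.00599) and Rpl11 at 0.92 ± 0.13 (n = 6, adjusted p = 0.000768). After print-tip loess 11 were higher and none was lower, with Rpl11 at 0.46 (adjusted p = 0.028) and Rpl5 at 0.89 ± 0.27 (adjusted p = 0.0605), and 19 passed when adjusted over the list alone. The list's mean was 0.19 with global loess and did not pass (adjusted p = 0.0704) unless array 2 or 3 was left out or all clones of a gene were averaged (adjusted p = 3.47e-05), and it was 0.22 after print-tip loess and passed (adjusted p = 3.6e-05), as it did in each of the 6 fits that left out 1 array (adjusted p at most 0.00466). That call was lost with an estimated correlation (adjusted p = 0.687, or 0.924 with global loess). The mean was 0.04 with median centring in place of loess (adjusted p = 0.859), and with the deposited value table it turned to -0.18 (adjusted p = 0.208).

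Of 54 oxidative phosphorylation genes, 11 were higher, 1 was lower (Ndufs3) and 42 did not pass (11 passed when adjusted over the list alone). The ATP synthase genes Atp5k and Atp5b were at 1.10 ± 0.13 (n = 6, adjusted p = 0.000399) and 1.05 ± 0.22 (n = 6, adjusted p = 0.00431), although the scanner files title the Atp5b clone procollagen XI alpha 2. After print-tip loess 7 were higher and Cox8a was lower, although 2 of the 4 Cox8a clones passed as higher there, with Atp5k at 0.34 and Atp5b at 1.00, and 16 passed when adjusted over the list alone. That list's mean was 0.19 (adjusted p = 0.0944), which passed without array 3 (adjusted p = 0.0421) and with all clones of a gene averaged (adjusted p = 0.0344), or 0.15 after print-tip loess, where it passed (adjusted p = 0.0339) but not without array 6 (adjusted p = 0.112). With an estimated correlation it did not pass (adjusted p = 0.746, or 0.924 with global loess).

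**Figure D3:**
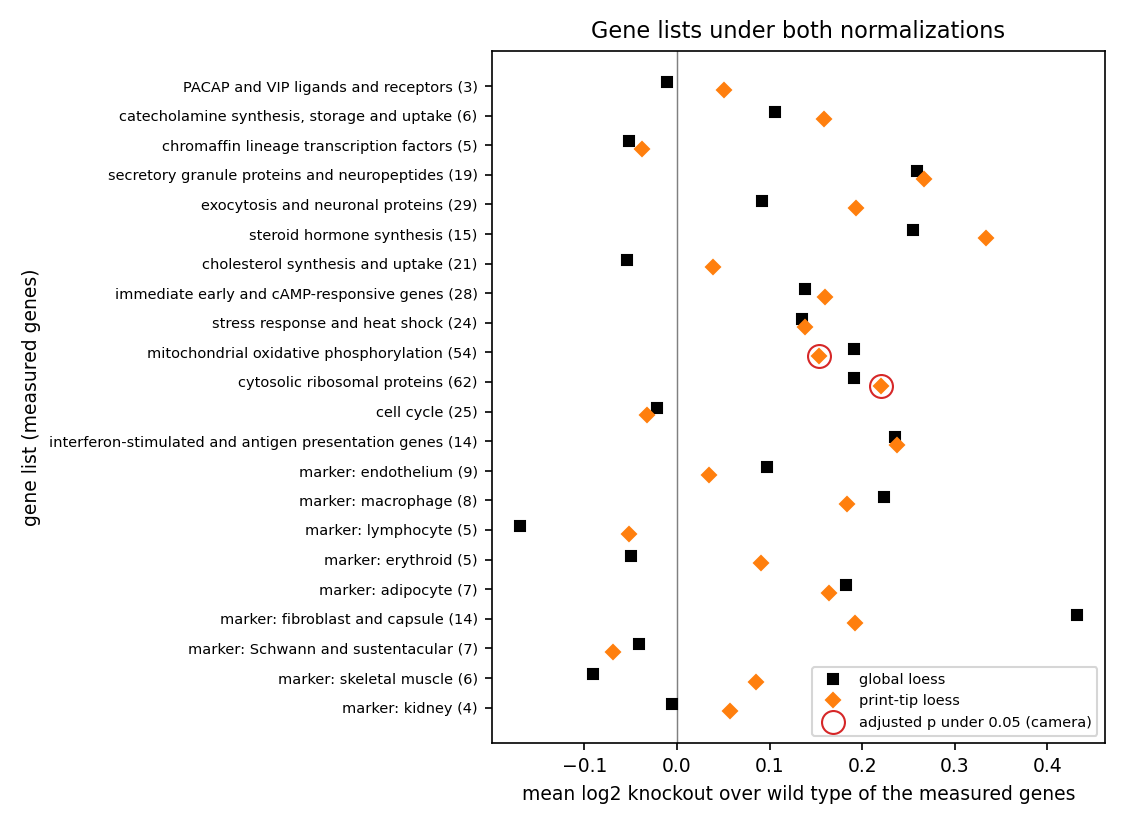
Mean log2 ratio of knockout over wild type (horizontal axis) of the measured genes of 22 gene lists (vertical axis, number of measured genes in parentheses) after global loess (black squares) and print-tip loess (orange diamonds); red rings mark lists with an adjusted p under 0.05 in camera. The rings mark the cytosolic ribosomal proteins at 0.22 and oxidative phosphorylation at 0.15, both after print-tip loess.

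Of 25 measured cell cycle genes, 5 were higher (Pcna, Aurkb, Mki67, Plk1 and Ccnd2), 4 were lower (Kif11, Birc5, Mcm7 and Top2a) and 16 did not pass, with 9 passing when adjusted over the list alone. Pcna was at 0.88 ± 0.18 and Kif11 at -0.81 ± 0.15 (SE, n = 6). After print-tip loess, at 0.29 and -0.20, neither passed, and Pcna ran from 0.06 to 0.40 there with 1 array left out. Aurkb at 1.45 and Birc5 at -0.47 did pass there, the same 2 as when adjusted over the list alone. The mean was -0.02 (adjusted p = 0.78; -0.08 to -0.06 without array 1, 3, 5 or 6), or -0.03 after print-tip loess (adjusted p = 0.081). Of 14 interferon-stimulated and antigen presentation genes, 4 were higher (Irf1, H2-Eb1, Stat2 and Irf9), 2 were lower (Ifit1 and Irf7) and 8 did not pass, with 6 passing when adjusted over the list alone. The other Stat2 clone passed as lower. The transcription factor gene Irf1 was at 0.95 ± 0.22 (n = 6, adjusted p = 0.0076) and at 1.23 ± 0.27 after print-tip loess (adjusted p = 0.0312), and the class II gene H2-Eb1 was at 0.83 ± 0.13 and at 0.40 ± 0.13 after print-tip loess (adjusted p = 0.0678). B2m (0.76), Ly6e (0.43) and Ifit1 (-0.35) also passed after print-tip loess, with 7 passing when adjusted over the list alone. The mean was 0.23 (adjusted p = 0.295; 0.14 without array 3), or 0.24 after print-tip loess (adjusted p = 0.151). No list passed with global loess in camera, where 3 of 22 had an unadjusted p under 0.05, and none in fry's test of whether a list moves one way on balance. Fry's mixed test, of change in either direction, had an adjusted p under 0.05 for 15 of the 22 lists, and neither fry test compares a list with other genes.

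Markers of other cell types that a dissected adrenal can hold were measured beside these groups. The list of fibroblast and capsule markers had the highest mean of all lists with global loess, 0.43 (adjusted p = 0.0594), which passed without array 2, 3 or 5 (adjusted p 0.0281 to 0.0421) and without arrays 2 and 4 (0.49, adjusted p = 0.00214) and with all clones of a gene averaged (adjusted p = 0.00051), and which was 0.19 after print-tip loess (adjusted p = 0.236), where 5 lists had higher means. It was 0.26 with median centring and -0.02 with the deposited value table. With an estimated correlation it did not pass (adjusted p = 0.924, or 0.765 after print-tip loess). Of its 14 measured genes 8 were higher and 2 were lower (Col3a1 and Dcn), led by the collagen gene Col1a1 at 1.64 ± 0.25 (SE, n = 6, adjusted p = 0.00104) and Nr2f2 at 1.20 ± 0.16 (n = 6, adjusted p = 0.000564). The lower calls were contradicted by other clones: 2 of the 4 Dcn clones and 1 of the 3 Col3a1 clones passed as higher. Both Col1a1 and Nr2f2 passed after print-tip loess, at 0.91 and 0.51, among 5 higher genes and 1 lower, Pdgfra at -0.32. When adjusted over the list alone, 10 passed, or 6 after print-tip loess. Of 8 macrophage markers, C1qb (0.94 ± 0.22, n = 6) and Cd68 (0.63 ± 0.20, n = 5) were higher and Laptm5 was lower (-0.43), with its other clone passing as higher, and C1qb alone passed after print-tip loess, at 0.88. Of 7 adipocyte markers, Scd1 (0.50) and Elovl3 (0.46) were higher, and after print-tip loess Scd1 passed at 0.66 while Elovl3 was at -0.07. The adipocyte list passed only with all clones of a gene averaged (0.34, adjusted p = 0.0344). In camera with an estimated correlation, on 1 clone per gene, it did not pass (adjusted p = 0.924, or 0.765 after print-tip loess).

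In the remaining marker lists no member passed after print-tip loess. With global loess the endothelial genes Emcn (0.58) and Eng (0.42) and the Schwann cell genes Ncam1 (0.44) and Pmp22 (0.42, with its other clone passing as lower) were higher, and the lymphocyte genes Jchain (-0.56) and Ptprc (-0.47), the erythroid gene Car2 (-0.37) and the muscle genes Eno3 (-0.61) and Mb (-0.36) were lower. After print-tip loess these 9 were at 0.31, -0.03, -0.17, 0.28, -0.17, -0.18, -0.01, 0.16 and -0.08 in that order. Leaving out 1 array ended the calls of Cd68 (arrays 3, 4 or 6; 0.40 to 0.64), Eng (arrays 1, 2, 3 or 5; 0.34 to 0.44), Ncam1 (array 4; 0.42), Pmp22 (arrays 1, 2, 3 or 4; 0.35 to 0.40), Ptprc (arrays 2 to 6; -0.52 to -0.34), Car2 (arrays 2 to 6; -0.42 to -0.30) and Mb (arrays 2 to 6; -0.41 to -0.28). None of the 4 kidney markers passed, Aqp1 having the smallest p at -0.22 ± 0.14 (-0.01 after print-tip loess). The marker lists other than that of fibroblasts and capsule had means of 0.22 for macrophages, 0.18 for adipocytes, 0.10 for endothelium, -0.04 for Schwann cells, -0.17 for lymphocytes, -0.05 for erythroid cells, -0.09 for muscle and -0.01 for kidney, with adjusted p from 0.657 to 0.938. After print-tip loess the means were 0.18, 0.16, 0.03, -0.07, -0.05, 0.09, 0.08 and 0.06 in the same order (adjusted p from 0.429 to 0.843), so that the sign turned for erythroid cells, muscle and kidney. With global loess and 1 array left out, the sign also turned for Schwann cells (0.02 without array 4 or 5), muscle (0.02 to 0.06 without array 2, 3, 4 or 6) and kidney (up to 0.03, without array 3). The endothelial mean was 0.05 without array 6 and 0.15 without array 1, and the erythroid mean -0.09 without array 4 and -0.01 without array 5. With global loess the median had the other sign for endothelium (-0.12), for erythroid cells (0.02) and for kidney (0.0017). When adjusted over the list alone, 3 macrophage markers passed with global loess. So did 2 each of the endothelial, lymphocyte, erythroid, adipocyte, Schwann cell and muscle markers, and 0 of kidney. With print-tip loess 2 macrophage markers, 1 adipocyte marker and 1 Schwann cell marker (Pmp22) passed in this way. None of the endothelial, lymphocyte, erythroid, muscle and kidney markers did. Neither X-zone marker was measured. Of the sex-linked genes, the Y-linked Eif2s3y was at 0.55 ± 0.14 (n = 6, adjusted p = 0.0105) and at 0.20 after print-tip loess (adjusted p = 0.199), and Xist, at 0.07, or -0.08 after print-tip loess, did not pass.

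Because the mice were of a mixed background, genes near the targeted locus were compared with the rest. Of 24 measured genes within 10 Mb of Adcyap1, 5 (20.8%) passed, against 3168 of 10214 other genes (31.0%; odds ratio 0.585, 95% interval 0.171 to 1.62, Fisher's exact p = 0.378, two-sided). After print-tip loess 2 of 24 and 1131 of 10214 passed (odds ratio 0.73, Fisher's exact p = 1). The interval includes both a lower and a higher share near the locus.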

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

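Of the tests in this part, those of the print block, of the array correlations and of the array slopes were chosen after the results were seen. The sign patterns and the test of the second background subtraction were set out before their results.

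Among 93 sets of 4 to 6 array values that were looked at, 3 held a value standing apart from the others, where chance gives about 4.7. For Mvd, a gene of cholesterol synthesis, array 3 was at -2.36, with the other 5 between -0.66 and 0.18. The mean of the endothelial marker list was 0.38 on array 6, with the others between -0.03 and 0.09. The median red signal over background was 4.74 on array 1, with the others between 1.13 and 2.08.

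The first pattern is the number of clones past the threshold, 8732 with global loess. Chance assignment of the sign is argued against by 32 patterns in which the log ratios of some arrays are turned round. Only 1 gave as many clones, the real one, and the highest of the others gave 1. After print-tip loess, with 3259 clones, it was again 1 of 32, with 2 clones as the highest other. No share below 1 of 32 was possible. Any effect shared by the arrays, of position or dye as well as of genotype, would give this result. The patterns therefore do not show how many calls are due to genotype. A position effect on the slide may account for part of the calls, since the print block held 48.7% of the variance of the mean log ratio, against at most 0.31% in 100 shuffles. A shift shared by all clones of a block is argued against as the whole cause, since after print-tip loess, which removes it, the lowest correlation between 2 arrays was still 0.174 over clones. A dye effect that repeats for the same clone on every array and a genotype effect cannot be told apart by these values, because no array had the dyes exchanged.

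The second pattern is that the log ratios were larger on some arrays than on others. The slope of an array's log ratios on the other 5 arrays' mean ranged from 0.348 (array 1) to 1.52 (array 4). The highest was 4.36 times the lowest, and after print-tip loess the slopes ran from 0.244 to 1.70. Standard errors were at most 0.00857, but they treat clones as independent, which clones of 1 print block are not. A slope also depends on how closely an array follows the others, so 4.36 is not a ratio of sizes. The SD of the log2 ratios was 0.342 on array 1 and 0.661 on array 4. Their mean correlations with the other arrays were 0.38 and 0.629. The unequal slopes argue against a genotype effect of 1 size on all 6 arrays as the whole of the signal. The slope fell with the median red signal over background, with Spearman's rho = -1 (exact permutation p = 0.0028, the smallest that 720 pairings can give; adjusted p = 0.0168 over 6 relations) and Pearson's r = -0.78 (exact permutation p = 0.0333, adjusted p = 0.172; -0.86 without the 2 arrays farthest from the median). After print-tip loess rho was -0.94 (exact permutation p = 0.0167, adjusted p = 0.0501) and r was -0.69 (exact permutation p = 0.0861). With global loess, rho against the green signal over background was 0.09 (exact permutation p = 0.919). Against the calibration constant, also with global loess, rho was -0.83 (exact permutation p = 0.0583, adjusted p = 0.117) and r was -0.75 (-0.94 without the 2 farthest arrays). After print-tip loess rho was 0.14 against the green signal (exact permutation p = 0.803) and -0.66 against the calibration constant (exact permutation p = 0.175). The relation was therefore not shown to be specific to the red signal. A weak red signal is a candidate cause of the larger ratios, while a genotype effect that differs in size between the RNAs compared on each array stays open as untested.

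The third pattern is that the deposited value table gave 90 clones past the threshold where the scanner values gave 8732. With the background subtracted a second time and loess kept, 2405 clones passed, which lies between the counts that had been set out for and against this as the whole cause. With the second subtraction and median centring in place of loess, 83 clones passed, against 9428 with median centring and a single subtraction, and the median standard error of a clone was 0.407 against 0.154. The second subtraction thus lowered the count both with loess and with median centring. Median centring in place of loess lowered it only together with the second subtraction. The second subtraction may act through the spread it adds to clones with weak red signal, which was not tested.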

How the results depend on the processing

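Normexp, the omission of arrays 2 and 4, and every alternative of the print-tip fit were chosen after seeing the data; the others had been fixed. The planned plain background subtraction coincided with the reported setting, since the deposited columns were already subtracted. The 8732 clones stayed within 1.5 times with no background correction (8913), normexp (8515), median centring (9428), scaling between arrays (9190), no quality filter (7438), a value on all 6 arrays (7469), trend and robust variances (8743) and array weights (11168). The count was 3259 after print-tip loess, 5365 with the clones above the median signal, where 14354 were tested, 90 with the deposited value table, 2234 without arrays 2 and 4, 3701 at an adjusted p under 0.01, and 4478 to 8656 with 1 array left out. Without the pairing of the channels on an array, that is without the replicate block, 152 clones passed. That setting also brought the mean signals of the arrays to the same distribution, so the share of the lost pairing was not told apart. The deposited value table also moved the median of all clones to 0.24. The 3259 clones of print-tip loess became 90 without arrays 2 and 4, 4926 with array weights, 1 at an adjusted p under 0.01, and 1 to 3768 with 1 array left out. The causes of these moves were not tested beyond the weighing given for the first 3 patterns.

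No gene list passed as reported. With print-tip loess 2 passed, and with arrays 2 and 4 also left out 3 (cytosolic ribosomal proteins, oxidative phosphorylation, exocytosis and neuronal proteins). One list, the fibroblast and capsule markers, passed with scaling between arrays (1), with a value on all 6 arrays (1), with the clones above the median signal (1) and without arrays 2 and 4 (1). With the mean over all clones of a gene in place of 1 clone 4 passed (cytosolic ribosomal proteins, oxidative phosphorylation, adipocyte markers, fibroblast and capsule markers), so these calls depended on that choice, and with 1 array left out 0 to 3. With an estimated correlation and with fry's test of movement one way on balance, 0 passed, as with the other settings; fry's mixed test passed 15 of 22. The mean of the exocytosis list fell to 0.0071 with median centring. Over all list and setting pairs 377 gave the same verdict, 19 passed newly and 62 changed the sign of a mean without passing. The ratio of the targeted gene, Adcyap1, was 5.318 with the deposited value table, a mean of arrays 3 and 5 alone, on both of which the twice-subtracted red value lay at the floor. On all 6 arrays its table values ran from -2.52 to 5.48, 2 of them negative. The odds ratio of the genes near Adcyap1 was 0.742 for 5 Mb and 0.702 for 20 Mb, with no call.

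Of 58 named genes past the threshold, 29 kept their call with print-tip loess and 1 with the deposited value table. Of the 45 that could be tested without arrays 2 and 4, 24 kept it. Without pairing, a setting that also equalised the mean signals of the arrays, 7 of the 58 kept it. With print-tip loess the sign turned for Qdpr (0.17), Msmo1 (0.0026), Eng (-0.0272), Elovl3 (-0.0714), Ncam1 (-0.17) and Eno3 (0.16), none of them past the threshold. With the deposited value table it turned for Natd1 (0.67), F8a (1.77), Eif2b5 (3.81), Taf1 (3.49), Qdpr (1.36), Mvd (1.45), Hsp90aa1 (-0.16), Rpl5 (-0.18), Jchain (0.18), Ptprc (3.32), Ncam1 (-0.51) and Eno3 (0.42), again without passing.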

Other observations

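The test of clones of the same gene was set out before its result, and that of Armt1 was chosen after its values were seen. Genes printed as several clones give a view that does not rest on 1 spot. Of 1958 genes with at least 3 tested clones, 31 had all clones past the threshold in the same direction with global loess, 27 of them higher. After print-tip loess there were 8, namely Eef1a1 with 12 of 12 clones, Rpl14 with 4 of 4, and Cst3, Dync1i2, Fip1l1, Idh1 and Myl12b, each with 3 of 3 clones higher, and Hs6st2 with 3 of 3 clones lower. Rpl14, Cst3 (cystatin C) and Idh1 (cytosolic isocitrate dehydrogenase) had all clones higher in both normalizations, with means of 0.65, 0.61 and 0.85 with global loess and of 0.47, 0.52 and 0.88 after print-tip loess. Clu, which encodes the secreted chaperone clusterin, had 5 of 5 clones higher with global loess (0.48 to 1.12) and 3 of 5 after print-tip loess. The 5 clones of the nuclear RNA Malat1 were all higher with global loess (0.44 to 1.83), and 1 of them passed after print-tip loess.

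A hypothesis is that part of the signal belongs to the gene and not to the place of the spot. Gene names were shuffled 100 times among clones of the same print block: the highest number of genes with all clones moving the same way was 17 with global loess, against the 31 observed, and 4 after print-tip loess, against 8. The excess lay in the higher direction, with 27 genes against a shuffled highest of 14, and 7 against 4 after print-tip loess. In the lower direction there was none, with 4 genes against 8, and 1 (Hs6st2) against 1. The values are compatible with a part of the ratio that follows the transcript among higher genes. Such a part may be an effect of genotype or a dye effect of the sequence, which clones of the same gene share. The shuffles held the print block but not the signal, which clones of the same gene can also share. Among clones above the median signal 37.4% passed, against 30.4% of all clones. An effect that depends on signal was therefore not told apart. The agreement was limited, since the Spearman correlation across genes between 2 clones of a gene was 0.274 with global loess and 0.209 after print-tip loess (4879 genes, which are not independent replicates), against 0.782 and 0.792 between 2 spots of the same clone (104 clones). Clones past the threshold in opposite directions occurred in 221 of the 1958 genes with global loess, against a shuffled mean of 300, and in 13 after print-tip loess, against 39.4.

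The log2 ratio of Armt1 varied less between arrays than the array slopes did. It lay between 2.30 and 3.08 on the 6 arrays, so that the highest was 1.34 times the lowest. The slopes differed by 4.36 times, but they also depend on correlation, and the SDs of the arrays ran only from 0.342 to 0.691. Armt1 was picked after its values were seen, and its range was not compared with that of other clones. Whether the scaling with weak red signal contributes to its ratio is therefore not decided. Armt1 was past the threshold in all 6 print-tip fits with 1 array left out (2.23 to 2.54). Armt1 was represented by 1 clone, so a property of that clone, including its dye effect, and a difference between the strains that made up the mixed background stay open, and neither was tested.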
